A study of Arabidopsis thaliana with 12 samples.

How the data were processed

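Whole Arabidopsis thaliana seedlings of 3 genotypes were profiled on 12 one-colour Agilent arrays, 4 arrays per genotype. Per the labels' protocols, the seedlings were 2 weeks old and grew on MS agar with 1% sucrose at 23 °C under 16 h light and 8 h dark. Per the same labels, 1 µg of total RNA was labelled with Cy3 for each array. Group and replicate number were taken from the sample titles. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

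The deposited scanner files hold a spot intensity on a linear scale, written by Agilent Feature Extraction 9.1.3.1 per the submitters' processing notes, with the background already subtracted in the processed intensity per the file headers. They also hold marks for outlier spots and for spots well above background. The authors' series value table, also an intensity, was set against the scanner files. Each of its columns was the processed intensity divided by a single constant per genotype (974 for wild type, 1077 for glk1 glk2 and 892 for GLK1-SRDX). Its column medians ran from 0.0798 to 0.168. Its values are linear and uncentred, and the origin of the constants is not given in the sources used here.

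For each array, log2 of the processed intensity was taken relative to the array's 75th percentile, which ran from 1562 to 2542 intensity units. Control spots and outlier spots (6 to 86 non-control spots per array) were left out, and repeated spots of a probe were averaged. Of 37478 non-control probes, 26236 carried an AGI locus (the Arabidopsis gene identifier) and 11242 did not. On each array 63.9% to 68.4% of probes were well above background, and 0 non-control spots were saturated. A probe was kept if it was well above background on at least 4 of the 12 arrays and unmarked on at least 3 arrays of every group. The brightest probe stood for a locus, which gave 20640 tested loci out of 25665. A single probe measured 20116 of them. Symbols came from the reference gene table of assembly TAIR10.1, which held 20521 of the tested loci, and 9093 had a symbol. The table was used for names and gene order only. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.144.

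Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 12 arrays, 9 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a gene comes from this fit unless an alternative is named. "Rose", "fell" and "changed" refer to this threshold. Among the named genes that passed, the 4 arrays of each group did not overlap those of the other, except for LHCB2.2 in glk1 glk2 and for HEMA1 and BHLH100 in GLK1-SRDX against wild type. Where a probe was not well above background on every array of its dimmer group, the fold is given as "at least N-fold", with the number of arrays that measured it. It compares the bright group's mean with the dim group's mean of, per array, the higher of the dim probe's signal and the lowest signal well above background. Genes were ranked by the fitted change. Before the data were examined, 22 gene lists were fixed, holding 359 genes of which 339 were tested. They cover light-harvesting antenna, chlorophyll synthesis, photosystem core, Calvin cycle, plastid-encoded genes, greening regulators, guard-cell transport, stomatal lineage, abscisic acid response, oxidative stress, salicylate defence, jasmonate response, circadian clock, flavonoid and anthocyanin synthesis, iron deficiency, starch and sugar, senescence, root, epidermis, phloem and flowering markers and reference genes. Of the plastid-encoded list 0 genes were measured, so 21 lists were tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists. Camera was repeated with an estimated correlation, with which 0 lists passed (3, 1 and 1 at an unadjusted p under 0.05 for glk1 glk2, GLK1-SRDX and the lines against each other). Fry was run for direction and for mixed change.

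The rule for named genes was fixed at the same time. In each comparison it took GLK1 and GLK2, the 6 largest rises and 6 largest falls among genes with a symbol that passed and whose groups did not overlap, and up to 3 passing members of each list with the largest change, or the member with the smallest p where none passed. Against wild type it also took KAT1, KAT2, AKT1, AKT2, GORK, SLAC1 and OST1. Some list members were left out of the text. FRO2, NAS2, ZIP8, BBX16, TIM17-1, FUM2, IAA29 and RLP37 were chosen after their values were seen.

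The arrays came from 3 slides, all scanned on the same day. Slides 1 and 2 each held 2 wild-type and 2 glk1 glk2 arrays, and slide 3 held all 4 GLK1-SRDX arrays, so slide and GLK1-SRDX cannot be told apart. Replicate numbers are shared by all groups in the labels. Deviations of same-numbered wild-type and glk1 glk2 arrays from their group means correlated at 0.319, 0.383, 0.464 and 0.757 across genes, which are not independent replicates. All were above 0.1, and these numbers were treated as pairs in an alternative fit with the replicate number as a block. Differently numbered arrays ran from -0.578 to 0.295, below every same-numbered value. Some of these also exceeded 0.1, namely glk1 glk2 replicate 3 with wild-type replicate 2 (0.295) and the reverse (0.165). The pairing comes from this check, since the labels do not state what a number stands for.

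The alternatives were quantile normalization, median scaling, normexp background correction (offset 50), no filter on dim probes, probes above background on all 12 arrays, the mean of a gene's probes, the series value table, only the 2 groups compared, the replicate number as a block, slide as a block, leaving out each array, a variance trend with robust estimation, and a 2-fold threshold. Normexp was planned on mean signals and run on the median signals that the files used here hold. The steps were tested on simulated data with 200 changed genes among 20640. For glk1 glk2 against wild type the fit recovered 40.3% of log2 changes of 0.5, 73.1% of changes of 1 and 83.3% of changes of 2, with 4.38% false calls. For GLK1-SRDX against wild type these were 26.9%, 67.2% and 90.9%, with 3.91% false calls. For GLK1-SRDX against glk1 glk2 they were 40.3%, 73.1% and 90.9%, with 6.21% false calls. In each of these simulations camera found the 1 shifted list and 0 of the others. The simulated genes were independent of one another, which real genes are not.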

Results

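The series compared seedlings that lack GLK1 and GLK2 (the glk1 glk2 double mutant) and seedlings that express GLK1-SRDX with wild-type Columbia seedlings. GLK1 and GLK2 are transcription factors that promote chloroplast development. GLK1-SRDX is GLK1 fused to SRDX, a repression domain derived from the SUPERMAN protein, expressed from the 35S promoter. Per the series title, the study was about tolerance to an air pollutant and stomatal closure. Each group had 4 arrays, and 20640 genes were tested.

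Both GLK transcripts were lower in glk1 glk2. GLK2 (AT5G44190) was 183-fold lower than in wild type (log2 fold change -7.51 ± 0.19 SE, n = 4 per group, limma adjusted p = 4.70e-09). GLK1 (AT2G20570) was 4.68-fold lower (-2.23 ± 0.28 SE, adjusted p = 0.00296). In GLK1-SRDX the GLK1 signal was 1.80-fold higher than in wild type (0.85 ± 0.28 SE, adjusted p = 0.0649) and GLK2 was 1.54-fold higher (0.62 ± 0.19 SE, adjusted p = 0.0513), and neither passed the threshold. Both passed without glk1 glk2 replicate 3 (adjusted p = 0.0234 and 0.048) or replicate 4 (adjusted p = 0.0158 and 0.021), and GLK2 also without wild-type replicate 4 (adjusted p = 0.0436). Over all alternatives GLK1 ran from 0.00649 to 0.404 and GLK2 from 0.0122 to 0.254. The arrays of the groups did not overlap for either gene, which gives an exact permutation p of 0.0286, the smallest that 70 arrangements allow. Each gene was read by 1 probe, and whether it lies in the part carried by the transgene or disrupted in the mutant is not known here.

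**Figure D1:**
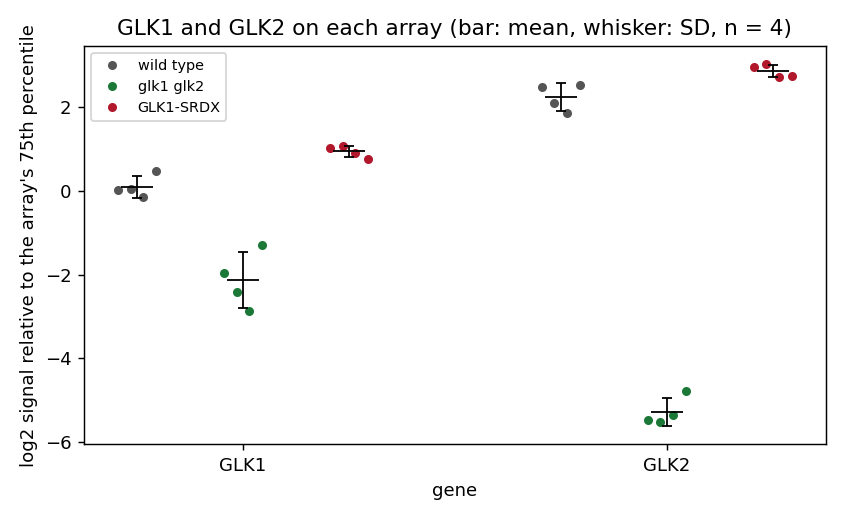
Log2 signal of GLK1 and GLK2 relative to each array's 75th percentile (vertical axis) on the 4 wild-type, 4 glk1 glk2 and 4 GLK1-SRDX arrays, as points, with the mean as a bar and the SD as a whisker. Mean GLK2 was 2.24 in wild type, -5.28 in glk1 glk2 and 2.86 in GLK1-SRDX, and mean GLK1 was 0.095, -2.13 and 0.94.

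The comparison of glk1 glk2 with wild type asks what loss of both genes does to the seedling transcriptome. Genes of the photosynthetic apparatus were lower in the mutant. Of 22 measured light-harvesting antenna genes, 16 fell, 0 rose and 6 did not pass (17 fell adjusted over the list alone, median log2 fold change -0.81, camera adjusted p = 5.41e-19, and adjusted p = 0.241 with an estimated correlation). LHCB1.4, a chlorophyll-binding protein of photosystem II, fell (234-fold, adjusted p = 3.09e-09), as did LHCB2.3 (6.39-fold, adjusted p = 0.0328) and LHCB2.2 (5.71-fold, adjusted p = 0.0486). Of 22 nuclear genes of the photosystem cores, 12 fell and 10 did not pass (18 fell adjusted over the list alone, median log2 fold change -0.72, camera adjusted p = 5.41e-19, and adjusted p = 0.271 with an estimated correlation). PSBQ2, of the oxygen-evolving complex, fell (5.50-fold, adjusted p = 1.26e-05), as did PSAE2 of photosystem I (4.71-fold, adjusted p = 9.13e-06) and PSAH2 (3.67-fold, adjusted p = 0.0140). Of 25 chlorophyll synthesis genes, 5 fell and 20 did not pass (6 fell adjusted over the list alone, median log2 fold change -0.28, camera adjusted p = 0.000320, and adjusted p = 0.699 with an estimated correlation). PORA, a protochlorophyllide oxidoreductase, fell (34.0-fold, adjusted p = 0.00104), as did GUN4 (2.62-fold, adjusted p = 0.0489) and HEME1 (1.75-fold, adjusted p = 0.0356). The chlorophyll list did not pass without glk1 glk2 replicate 3 (adjusted p = 0.154, and 5.57e-12 to 0.699 over its alternatives). Its median was -0.14 without that array and -0.15 without wild-type replicate 4. Root markers were lower in this comparison too (median -0.76). With the root-marker level of each array as a covariate, an alternative chosen after the data were seen, the chlorophyll median was -0.56 (adjusted p = 5.57e-12), and the antenna and core medians were -0.99 and -1.02.

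The iron-deficiency list and the flavonoid and anthocyanin list were also lower in glk1 glk2. Of 9 measured iron-deficiency genes, 5 fell and 4 did not pass (6 fell and 1 rose adjusted over the list alone, median log2 fold change -3.19, camera adjusted p = 1.40e-06, and adjusted p = 0.241 with an estimated correlation). BHLH100, a transcription factor of the iron-deficiency response, fell (at least 67.2-fold, adjusted p = 0.00101), being well above background on 0 of the 4 mutant arrays. IRT1, the main iron transporter of the root, fell (at least 4.46 on the log2 scale, adjusted p = 0.0139; above background on 3 of 4 mutant arrays), as did BHLH38 (at least 15.8-fold, adjusted p = 0.00852; above background on 1 of 4). A dimmer IRT1 probe, above background on 4 of the 12 arrays, stood at -2.71, against -4.57 for the probe used. Of 17 flavonoid and anthocyanin genes, 5 fell and 12 did not pass (6 fell and 1 rose adjusted over the list alone, median log2 fold change -0.20, camera adjusted p = 0.000320, and adjusted p = 0.360 with an estimated correlation). DFR, dihydroflavonol reductase, fell (at least 8.50-fold, adjusted p = 0.00485; above background on 2 of 4), as did LDOX, which acts after DFR (at least 4.81-fold, adjusted p = 0.00290; above background on 0 of 4), and TT19, a glutathione transferase of anthocyanin transport (at least 8.80-fold, adjusted p = 0.00397; above background on 3 of 4). Requiring signal on all arrays removes genes that fell to background on at least 1 mutant array, BHLH100, BHLH38, IRT1, DFR, LDOX and TT19 among them, and so selects against the change tested. Neither list passed with what that filter leaves (median -0.75, adjusted p = 0.197, and 3.15e-11 to 0.24 over its alternatives, for iron; median -0.011, adjusted p = 0.499, and 1.81e-06 to 0.499, for flavonoids). Median scaling, which moved all genes by 0.19, put the flavonoid median at -0.011. That median was -0.45 without a filter, -0.33 without wild-type replicate 3 and -0.46 and -0.35 without glk1 glk2 replicate 3 or 4. Markers of root tissue moved with these groups, with a median over 20 markers of -0.76 (camera adjusted p = 0.000115, and adjusted p = 0.650 with an estimated correlation). In limma 0 root markers passed by themselves (9 had an unadjusted p under 0.05; 0 adjusted over the list alone), and the mutant arrays ran from -2.07 to 0.18 around the wild-type mean. The root median was -1.37 without glk1 glk2 replicate 3 and -0.47 without both arrays numbered 4 of wild type and glk1 glk2. On glk1 glk2 replicate 3, where the root list stood at 0.18, the iron list was at -2.09 and the flavonoid list at -0.44. On wild-type replicate 3, which pairs with it, they were at -0.0019, -0.70 and -0.37, so little of the flavonoid difference remained within this pair. Both lists also passed with the root-marker covariate (medians -3.35 and -0.25, adjusted p = 1.31e-05 and 0.000251).

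Oxidative stress genes were higher in glk1 glk2, with 3 of 26 rising and 23 not passing (6 rose adjusted over the list alone, median log2 fold change 0.25, camera adjusted p = 0.000797, and adjusted p = 0.295 with an estimated correlation). FSD1, an iron superoxide dismutase, rose (1.91-fold, adjusted p = 0.00204), as did SAPX, a stromal ascorbate peroxidase (1.69-fold, adjusted p = 0.00472), and CSD2, a copper/zinc superoxide dismutase (1.44-fold, adjusted p = 0.0376). The list did not pass with the root-marker covariate (adjusted p = 0.0723, and 0.000104 to 0.295 over its alternatives). The covariate lowered its median to 0.082, while the median SE of its members was 0.161 before and 0.153 after. The root markers were lower beside this list. Its median was 0.13 without glk1 glk2 replicate 4. Among the largest rises were SEP3, a floral MADS-box factor (4.67-fold, adjusted p = 0.0200), NEET, an iron-sulfur protein (3.03-fold, adjusted p = 0.0134), MEE3 (2.58-fold, adjusted p = 0.0339) and BCB, a blue copper-binding protein (2.19-fold, adjusted p = 0.0173). UNE15 was among the largest falls (at least 27.3-fold, adjusted p = 8.33e-05; above background on 2 of 4 mutant arrays).

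Guard-cell transport genes gave 1 rise of 28 (1 rose adjusted over the list alone), ALMT6 (1.86-fold, adjusted p = 0.00333). KAT1, an inward potassium channel of guard cells, did not pass (-0.80, adjusted p = 0.157). With the replicate number as a block on the 8 arrays it did (adjusted p = 0.0449, and 0.042 to 1.00 over its alternatives). EPFL9, a peptide that promotes stomatal formation, rose (1.55-fold, adjusted p = 0.0207) as the 1 passing member of 18 stomatal lineage genes (1 rose adjusted over the list alone). Of 19 salicylate defence genes, 2 fell (3 fell and 1 rose adjusted over the list alone), ICS1, of salicylate synthesis (2.40-fold, adjusted p = 0.00852), and EDS1 (1.42-fold, adjusted p = 0.0400). Of 19 Calvin cycle genes TIM rose (1.37-fold, adjusted p = 0.0400; 1 rose adjusted over the list alone), of 18 clock genes PRR5 (1.45-fold, adjusted p = 0.0356; 1 rose adjusted over the list alone) and of 9 starch and sugar genes SEX1 (1.29-fold, adjusted p = 0.0368; 1 rose adjusted over the list alone). COR47 fell (1.43-fold, adjusted p = 0.0476) as the 1 of 19 abscisic acid genes that passed (1 fell adjusted over the list alone). In limma, 0 members passed among 17 greening regulators, 16 jasmonate genes, 11 senescence genes, 8 epidermis markers, 4 phloem markers, 4 flowering markers and 8 reference genes, of which 3, 2, 3, 0, 0, 1 and 1 had an unadjusted p under 0.05. Adjusted over the list alone, 1 flowering marker rose and 0 of the others passed. Among the lists that camera did not pass, the clock list had the smallest p (median 0.27, adjusted p = 0.0620). Signs differed within 3 of them. The guard-cell list had a median of 0.064, a mean of -0.025 and a camera test pointing upwards (adjusted p = 0.924), the jasmonate list a median of 0.045, a mean of 0.094 and a camera test pointing downwards (adjusted p = 0.940) and the flowering markers a median of 0.28, a mean of -0.014 and a camera test pointing upwards (adjusted p = 0.387). With genes below background at their bound the flowering median was 0.21.

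In all, 671 of 20640 genes changed in glk1 glk2, 441 higher and 230 lower, and 132 of them at least 2-fold (14 higher and 118 lower). The groups did not overlap for 9.66% of genes, against a chance mean of 2.86%. Genes move together, so a single split can lie far from that mean, and the contrast is not a test of genotype. With the replicate number as a block on the 8 wild-type and glk1 glk2 arrays, 1365 genes changed. That fit ended the calls of EDS1 (adjusted p = 0.101), EPFL9 (adjusted p = 0.07), MEE3 (adjusted p = 0.0628), ICS1 (adjusted p = 0.0586), IRT1 (adjusted p = 0.0514) and TIM (adjusted p = 0.0501), whose adjusted p ran from 0.00810 to 1.00, 0.0112 to 1.00, 0.012 to 1.00, 0.00062 to 1.00, 0.0014 to 1.00 and 0.00491 to 1.00 over all alternatives. With slide as a block 674 genes changed. Each slide with both groups held them equally, so this block cannot move a fold change or a list's median. It ended the calls of LHCB2.2 (adjusted p = 0.0653), GUN4 (adjusted p = 0.0653) and COR47 (adjusted p = 0.0539), which ran from 0.00725 to 1.00, 0.00757 to 1.00 and 0.0281 to 1.00 over all alternatives. Within slide 1 the medians were -0.65 for antenna, -0.57 for core, -0.18 for chlorophyll, -3.21 for iron, -0.25 for flavonoid, 0.26 for oxidative stress and -1.10 for root genes, with GLK2 at -7.77 and GLK1 at -2.21. Within slide 2 they were -1.02, -0.89, -0.39, -3.13, -0.28, 0.23 and -0.63, with GLK2 at -7.26 and GLK1 at -2.24. In limma 20 genes passed within slide 1 and 0 within slide 2 (4936 and 298 at an unadjusted p under 0.05).

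The count in glk1 glk2 moved with single arrays. It was 229, 267 and 354 without wild-type replicate 1, 2 or 4, 286, 326 and 3177 without glk1 glk2 replicate 1, 2 or 3, and 407 without GLK1-SRDX replicate 2. Passing lists numbered 7, and 12 without wild-type replicate 4. Of the 33 named genes called besides GLK1 and GLK2, 17 passed whichever array was left out, namely ALMT6, BHLH100, BHLH38, DFR, FSD1, ICS1, LDOX, LHCB1.4, NEET, NRPD4, PORA, PSAE2, PSAH2, PSBQ2, SAPX, TT19 and UNE15. The most calls, 15, ended without wild-type replicate 2. Of the calls 65.7% were higher, against 90.3% of 1654 calls with median scaling and 2.94% of 136 calls from the series values.

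**Figure D2:**
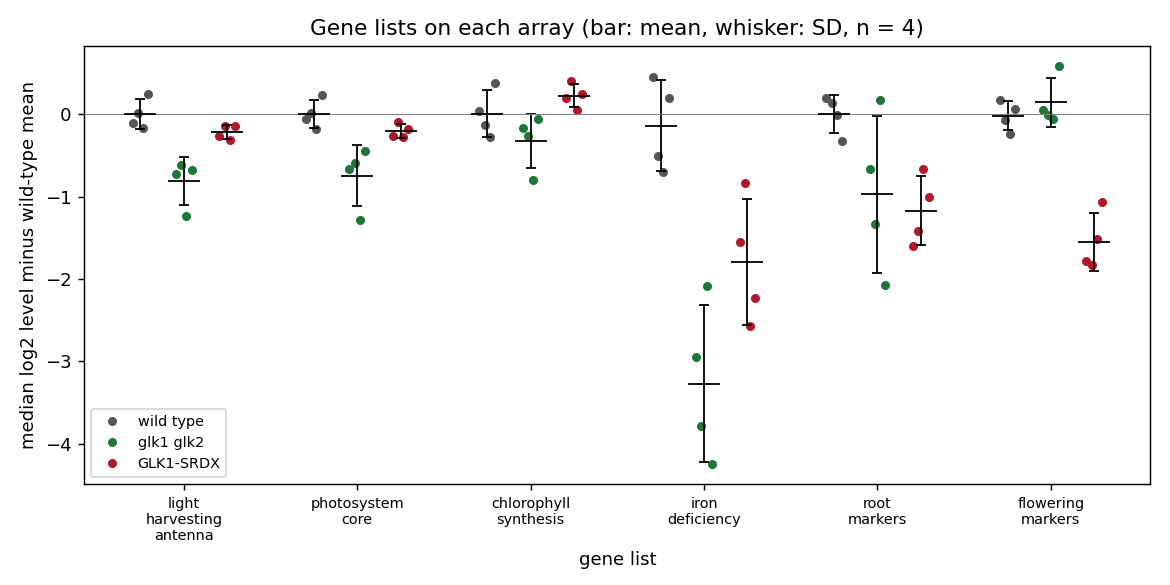
Median log2 level of 6 gene lists on each array relative to the wild-type mean of each gene (vertical axis), for 4 wild-type, 4 glk1 glk2 and 4 GLK1-SRDX arrays, as points, with the mean as a bar and the SD as a whisker. The glk1 glk2 arrays lie from -4.25 to -2.09 for the iron-deficiency list and from -1.23 to -0.61 for the antenna list, and the GLK1-SRDX arrays lie from -1.83 to -1.07 for the flowering markers.

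The comparison of GLK1-SRDX with wild type asks what the chimeric repressor does. Genes of stomatal movement were lower relative to all genes. Of 28 measured guard-cell transport and signalling genes, 5 fell, 0 rose and 23 did not pass (7 fell and 1 rose adjusted over the list alone, median log2 fold change -0.21, camera adjusted p = 0.00416, and adjusted p = 0.748 with an estimated correlation). The list did not pass fry's direction test (adjusted p = 0.0617). Median scaling moved all genes by 0.18 and put the list median at -0.023. Root markers were lower in the same comparison (median -0.98). With the root-marker covariate the guard-cell median was -0.16 (adjusted p = 0.027, and 0.00104 to 0.748 over its alternatives). Root-marker levels of the GLK1-SRDX and wild-type arrays did not overlap. The covariate therefore extends a slope beyond levels they share, here and wherever it is used for GLK1-SRDX against wild type. KAT1 fell (3.84-fold, adjusted p = 0.00173), as did MYB61, a transcription factor of stomatal aperture (4.31-fold, adjusted p = 0.0115), and BLUS1, a kinase of blue-light opening (1.62-fold, adjusted p = 0.0435). KAT2 (-0.53, adjusted p = 0.0688), AKT1 (-0.93, adjusted p = 0.0536), AKT2 (-0.30, adjusted p = 0.714), GORK (-0.29, adjusted p = 0.217), SLAC1 (-0.15, adjusted p = 0.513) and OST1 (0.047, adjusted p = 0.855) did not pass. The sign of AKT2, GORK, SLAC1 and OST1 depended on the setting. AKT1 passed in 10 of 25 alternatives (adjusted p from 0.0124 to 0.286), those without glk1 glk2 replicate 3 (adjusted p = 0.0155) or replicate 4 (adjusted p = 0.0208) among them. The 10 include the replicate number as a block and slide as a random block, which do not test this call. The GLK1-SRDX numbers were not taken as pairs, and slide and GLK1-SRDX cannot be told apart. Within glk1 glk2, AKT1 was highest on replicate 3 (0.48 around the wild-type mean) and lowest on replicate 4 (-1.08). Those arrays held the highest and lowest root-marker levels. Within GLK1-SRDX it was least lowered on replicate 3 (-0.51), again the array of highest root-marker level. The fall of AKT1 is therefore not separated from that of the root markers. KAT2 passed in 2 of 25 (from 0.0438 to 0.533), without glk1 glk2 replicate 3 (adjusted p = 0.0438) and with the root-marker covariate. GORK passed in 1 of 25 (from 0.0479 to 0.649), with only the 2 groups compared. In glk1 glk2 these 6 stood at 0.29, -0.32, 0.40, -0.36, 0.16 and -0.071, none passing except GORK without glk1 glk2 replicate 3 (adjusted p = 0.0238, and 0.0238 to 1.00 over its alternatives). There the sign of AKT1, AKT2 and OST1 depended on the setting.

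**Figure D3:**
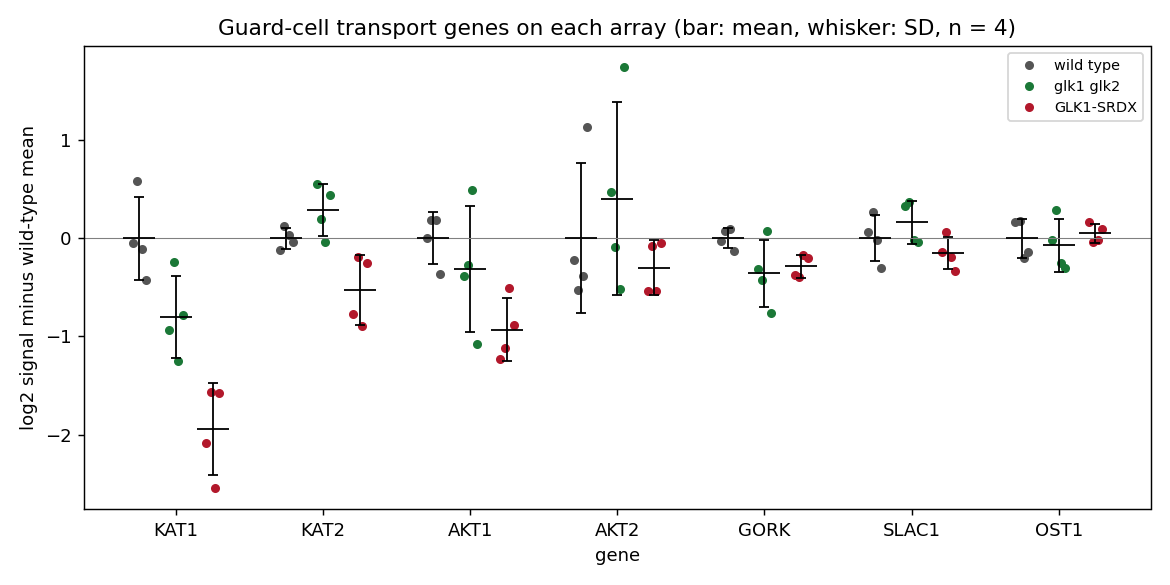
Log2 signal minus the wild-type mean (vertical axis) of 7 genes of stomatal movement on 4 wild-type, 4 glk1 glk2 and 4 GLK1-SRDX arrays, as points, with the mean as a bar and the SD as a whisker. KAT1 lies from -2.54 to -1.57 on the GLK1-SRDX arrays and from -0.42 to 0.58 on the wild-type arrays.

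Markers of the floral transition and of root tissue were lower in GLK1-SRDX as well. All 4 flowering markers fell (4 fell adjusted over the list alone; median -1.66, or -1.25 with genes below background at their bound; camera adjusted p = 0.000344, and adjusted p = 0.188 with an estimated correlation). FT, which encodes the mobile flowering signal, fell (at least 3.23-fold, adjusted p = 0.0265; above background on 1 of 4 GLK1-SRDX arrays), as did AP1 (at least 1.43-fold, adjusted p = 0.0170; above background on 0 of 4 GLK1-SRDX and 2 of 4 wild-type arrays) and FUL (2.58-fold, adjusted p = 0.00138). Of 20 root markers, 5 fell and 15 did not pass (11 fell and 1 rose adjusted over the list alone, median log2 fold change -0.98, camera adjusted p = 0.000344, and adjusted p = 0.944 with an estimated correlation). ADF8, an actin-depolymerizing factor, fell (4.28-fold, adjusted p = 0.0182), as did PER64 (3.40-fold, adjusted p = 0.0382) and CASP1, of the endodermal Casparian strip (3.37-fold, adjusted p = 0.0374). Of 9 iron-deficiency genes, 2 fell and 7 did not pass (7 fell and 1 rose adjusted over the list alone, median log2 fold change -1.76, camera adjusted p = 0.0103, and adjusted p = 0.748 with an estimated correlation), BHLH100 (8.02-fold, adjusted p = 0.0415) and FIT, a regulator of iron uptake (2.38-fold, adjusted p = 0.0468). The root markers moved with the iron list here too. The iron list did not pass with the root-marker covariate (adjusted p = 0.115), which brought its median to -0.99 while the median SE of its members was 0.638 before and 0.636 after. Without both arrays numbered 4 of wild type and glk1 glk2 it did not pass at a median of -1.74, close to that with all arrays (adjusted p = 0.0597). Its adjusted p ran from 0.000380 to 0.748 over its alternatives. It did not pass with probes above background on all arrays either (median -0.70, adjusted p = 0.582), a filter that removes BHLH100, BHLH38 and IRT1 for falling to background on glk1 glk2 arrays.

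By camera at its preset correlation, the antenna and core lists were lower in GLK1-SRDX relative to all genes. In each, 21 of 22 genes had a negative log2 fold change, and 1 fell by itself, LHCB4.3 (2.85-fold, adjusted p = 0.000722) and PSBQ2 (2.23-fold, adjusted p = 0.000722), and 1 in each fell adjusted over the list alone. The antenna median was -0.22 (camera adjusted p = 0.00591, and adjusted p = 0.944 with an estimated correlation) and the core median -0.20 (camera adjusted p = 0.00416, and adjusted p = 0.944 with an estimated correlation). The estimated correlations were 0.599 and 0.792, against the preset 0.01. Neither list passed fry's direction test (adjusted p = 0.411 and 0.416). Median scaling, which moved all genes by 0.18, put the medians at -0.032 and -0.016. Without wild-type replicate 4 neither list passed (medians -0.16 and -0.13, adjusted p = 0.071 and 0.0595). With the root-marker covariate the medians were -0.55 and -0.52 (adjusted p = 3.93e-08 and 1.18e-09), and root markers were lower in this comparison (median -0.98). The root-marker level ran from 0.305 to 0.870 on the wild-type arrays and from -0.836 to 0.0015 on the GLK1-SRDX arrays. These ranges do not overlap, so the adjusted medians extend a slope beyond shared levels. Over all alternatives the lists ran from 3.93e-08 to 0.944 and 1.18e-09 to 0.944. PORA fell (21.0-fold, adjusted p = 0.000707), as did CHLH, a subunit of magnesium chelatase (1.85-fold, adjusted p = 0.0337), while 3 of the 25 chlorophyll synthesis genes rose (2 fell and 5 rose adjusted over the list alone), HEMA1 among them (1.43-fold, adjusted p = 0.0478). Oxidative stress genes were higher, with 5 of 26 rising and 21 not passing (6 rose adjusted over the list alone, median log2 fold change 0.25, camera adjusted p = 0.00951, and adjusted p = 0.748 with an estimated correlation). FSD2 rose (2.04-fold, adjusted p = 0.000348), as did the ascorbate peroxidases APX1 (log2 fold change 0.59, adjusted p = 0.0123) and SAPX (1.47-fold, adjusted p = 0.00675). This list narrowly missed the threshold with normexp (median 0.24, adjusted p = 0.0507) and with probes above background on all arrays (median 0.23, adjusted p = 0.0506), at about the same size. With the root-marker covariate it did not pass at a median of 0.17 (adjusted p = 0.285), the median SE of its members being 0.161 before and 0.161 after. It ran from 0.0027 to 0.748 over its alternatives.

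Defence and hormone genes changed in both directions. Of 19 salicylate defence genes 3 rose and 2 fell (4 fell and 3 rose adjusted over the list alone), and SARD1, a regulator of salicylate synthesis, rose (3.83-fold, adjusted p = 0.0129), as did PR5 (2.15-fold, adjusted p = 0.0141). Of 16 jasmonate genes 3 rose and 2 fell (2 fell and 3 rose adjusted over the list alone). AOC1, of jasmonate synthesis, rose (at least 3.97-fold, adjusted p = 0.0102; above background on 3 of 4 wild-type arrays), as did CORI3 (3.19-fold, adjusted p = 0.00208), while the defensin PDF1.2B fell (at least 6.54-fold, adjusted p = 0.0279; above background on 3 of 4 GLK1-SRDX arrays). Of 19 abscisic acid genes 3 rose and 1 fell (1 fell and 4 rose adjusted over the list alone), with NCED3, of abscisic acid synthesis, falling (2.26-fold, adjusted p = 0.0358) and HAI1 rising (2.14-fold, adjusted p = 0.0229). EPFL9 rose (1.84-fold, adjusted p = 0.00118) and MYB88, which limits divisions in the stomatal lineage, fell (2.37-fold, adjusted p = 0.0227), the 2 of 18 stomatal lineage genes that passed (1 fell and 1 rose adjusted over the list alone). NAP, a senescence regulator, fell (2.85-fold, adjusted p = 0.0285) as 1 of 11 (1 fell adjusted over the list alone). Of 9 starch and sugar genes BAM5, a beta-amylase, fell (log2 fold change -1.14, adjusted p = 0.0458) and SEX1 rose (1.26-fold, adjusted p = 0.0203; 1 fell and 1 rose adjusted over the list alone). RBCS2B, a small subunit of Rubisco, fell (1.74-fold, adjusted p = 0.00850) as 1 of 19 Calvin cycle genes (1 fell adjusted over the list alone), and TT7 (1.36-fold, adjusted p = 0.0421) as 1 of 17 flavonoid genes (0 adjusted over the list alone). In limma, 0 of 18 clock genes, 17 greening regulators, 8 epidermis markers, 4 phloem markers and 8 reference genes passed, and 0 adjusted over the list alone; 1, 3, 5, 0 and 2 had an unadjusted p under 0.05. Among the lists that camera did not pass, chlorophyll synthesis had the smallest p (median 0.25, adjusted p = 0.146). Signs differed within the salicylate list, with a median of 0.049, a mean of 0.20 and a camera test pointing downwards (adjusted p = 0.928), the jasmonate list, with a median of 0.19, a mean of -0.010 and a camera test pointing upwards (adjusted p = 0.564), and the starch and sugar list, with a median of 0.21, a mean of -0.033 and a camera test pointing upwards (adjusted p = 0.646).

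The largest rise was the SUP probe, at least 15670-fold higher in GLK1-SRDX than in wild type (adjusted p = 1.28e-05), with wild type above background on 2 of 4 arrays. SUP encodes SUPERMAN, the protein from which the SRDX domain was derived, and whether the probe reads SUP or the transgene is not known here. Other large rises were CWINV5, a cell wall invertase (at least 22.5-fold, adjusted p = 0.000168; above background on 0 of 4 wild-type arrays), DIN2, a beta-glucosidase (9.04-fold, adjusted p = 0.00176), NATA1 (at least 6.17-fold, adjusted p = 0.0465; above background on 3 of 4), CYP76C2 (at least 3.94-fold, adjusted p = 0.0262; above background on 2 of 4) and TH8, a thioredoxin (5.99-fold, adjusted p = 0.000559). Among the largest falls, besides PORA, were CRK4, a receptor-like kinase (at least 18.1-fold, adjusted p = 0.00224), CASP5 (at least 4.32 on the log2 scale, adjusted p = 0.00263) and PRF4, a profilin (at least 8.78-fold, adjusted p = 0.00406), each above background on 2 of 4 GLK1-SRDX arrays. MES18 (at least 6.74-fold, adjusted p = 0.000189) and TPS03, a terpene synthase (at least 4.60-fold, adjusted p = 0.00602), were above background on 0 of the 4. In all, 2972 genes changed, 1671 higher and 1301 lower, and 876 at least 2-fold (268 higher and 608 lower). The groups did not overlap for 28.1% of genes, against a chance mean of 2.86%, from which a single split can lie far.

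All 4 GLK1-SRDX arrays shared a slide that held no other group, so slide and genotype cannot be told apart. The count was 1599 and 1708 without wild-type replicate 1 or 2 and 1581, 1523 and 1826 without GLK1-SRDX replicate 1, 2 or 3. Of the 46 named genes called, 24 passed whichever array was left out, namely AOC1, APX1, CASP5, CORI3, CRK4, CWINV5, DIN2, EPFL9, FSD2, FUL, KAT1, LHCB4.3, MES18, MYB61, PORA, PR5, PRF4, PSBQ2, RBCS2B, SAPX, SARD1, SUP, TH8 and TPS03. The most calls, 20, ended without GLK1-SRDX replicate 1. Of the calls 56.2% were higher, against 78.9% of 4414 calls with median scaling.

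GLK1-SRDX was also set against glk1 glk2, which tests whether the changes of the lines against the shared wild type differ. Antenna, photosystem core and chlorophyll synthesis genes were higher in GLK1-SRDX, while Calvin cycle genes, given below, were lower relative to all genes. Of 22 antenna genes, 12 were higher, 1 was lower and 9 did not pass (1 lower and 15 higher adjusted over the list alone, median log2 fold change 0.57, camera adjusted p = 4.34e-08, and adjusted p = 0.461 with an estimated correlation). Among them were LHCB1.4 (216-fold, adjusted p = 2.00e-09), LHCB4.2 (4.64-fold, adjusted p = 4.69e-06) and LHCB3 (3.39-fold, adjusted p = 0.000906). Of 22 core genes 9 were higher (12 higher adjusted over the list alone, median log2 fold change 0.47, camera adjusted p = 6.28e-09, and adjusted p = 0.461 with an estimated correlation), PSAE2 (3.73-fold, adjusted p = 2.20e-05) among them, and the median was 0.28 without glk1 glk2 replicate 3. Of 25 chlorophyll synthesis genes 8 were higher (10 higher adjusted over the list alone, median log2 fold change 0.55, camera adjusted p = 4.60e-07, and adjusted p = 0.461 with an estimated correlation), including CAO, which makes chlorophyll b (2.45-fold, adjusted p = 0.0404), and PORB (2.02-fold, adjusted p = 0.00536). Of 17 flavonoid genes 5 were higher and 1 lower (2 lower and 5 higher adjusted over the list alone, median log2 fold change 0.41, camera adjusted p = 0.0134, and adjusted p = 0.461 with an estimated correlation). The median was 0.32 with genes below background at their bound. DFR was higher (at least 6.14-fold, adjusted p = 0.00374; above background on 2 of 4 glk1 glk2 arrays). Of 9 iron genes 2 were higher (5 higher adjusted over the list alone, median log2 fold change 2.09, camera adjusted p = 0.0198, and adjusted p = 0.461 with an estimated correlation), BHLH100 (at least 8.37-fold, adjusted p = 0.00503; above background on 0 of 4 glk1 glk2 arrays) and BHLH101 (4.26-fold, adjusted p = 0.0212). The median was 1.92 with such bounds. The root markers had a median of -0.15, and 0 of 20 passed in limma (2 at an unadjusted p under 0.05; 0 adjusted over the list alone).

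Guard-cell genes were lower in GLK1-SRDX than in glk1 glk2 relative to all genes, 5 of 28 passing (5 lower adjusted over the list alone, median log2 fold change -0.27, camera adjusted p = 0.000680, and adjusted p = 0.461 with an estimated correlation), though their median was 0.015 with the series values, which moved all genes by 0.29. These included KAT1 (log2 fold change -1.14, adjusted p = 0.0316), ALMT6 (1.98-fold, adjusted p = 0.000757) and MYB60, a regulator of stomatal opening (1.83-fold, adjusted p = 0.00662). Of 4 flowering markers 3 were lower (3 lower adjusted over the list alone, median log2 fold change -1.81, camera adjusted p = 2.08e-05, and adjusted p = 0.107 with an estimated correlation), with FUL (4.24-fold, adjusted p = 0.000266) and SOC1 (2.39-fold, adjusted p = 0.000527) among them. The median was -1.10 with genes below background at their bound. Of 19 Calvin cycle genes 1 was lower (1 lower adjusted over the list alone, median log2 fold change -0.20, camera adjusted p = 0.0134, and adjusted p = 0.832 with an estimated correlation), RBCS2B (2.49-fold, adjusted p = 0.000906). The median was 0.090 with the series values, by that move of all genes. Of 18 clock genes 2 were lower (2 lower adjusted over the list alone, median log2 fold change -0.21, camera adjusted p = 0.0316, and adjusted p = 0.461 with an estimated correlation), RVE1 (2.13-fold, adjusted p = 0.0373) and PRR5 (1.41-fold, adjusted p = 0.0233). That move put the clock median at 0.072. Of 19 salicylate genes 4 were higher and 3 lower (3 lower and 5 higher adjusted over the list alone), with SARD1 (4.88-fold, adjusted p = 0.00737) and ICS1 (2.97-fold, adjusted p = 0.00111) higher. Of 16 jasmonate genes 3 were higher and 1 lower (3 lower and 5 higher adjusted over the list alone), and of 26 oxidative stress genes 4 were higher and 2 lower (2 lower and 4 higher adjusted over the list alone). Of 19 abscisic acid genes 3 were higher (4 higher adjusted over the list alone), COR15A, a cold-regulated gene, among them (3.75-fold, adjusted p = 0.00262). BAM5 was lower (3.37-fold, adjusted p = 0.00938) as 1 of 9 starch genes (1 lower and 1 higher adjusted over the list alone), and ACT2, an actin, (1.38-fold, adjusted p = 0.0231) as 1 of 8 reference genes (1 lower and 1 higher adjusted over the list alone). In limma, 0 of 18 stomatal lineage genes, 17 greening regulators, 11 senescence genes, 8 epidermis and 4 phloem markers passed, with 1, 6, 3, 5 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 2 senescence genes were higher and 1 lower, and 1 epidermis marker was higher and 2 lower. Among the lists that camera did not pass, the abscisic acid list had the smallest p (median 0.18, adjusted p = 0.0551). Signs differed within the jasmonate list, with a median of 0.27, a mean of -0.10 and a camera test pointing upwards (adjusted p = 0.457), and the oxidative stress list, with a median of -0.045, a mean of 0.0046 and a camera test pointing downwards (adjusted p = 0.907).

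The SUP probe was at least 23152-fold higher in GLK1-SRDX than in glk1 glk2 (adjusted p = 1.71e-06), with 0 glk1 glk2 arrays above background. Among the largest falls were CRK4 (at least 21.8-fold, adjusted p = 0.00254), CHAT, an acetyltransferase (at least 10.9-fold, adjusted p = 0.00518), and PDF1.2B (at least 13.9-fold, adjusted p = 0.00873), above background on 2, 1 and 3 of 4 GLK1-SRDX arrays. In all, 1911 genes differed, 1172 higher and 739 lower. The count was 1084 without glk1 glk2 replicate 1 and 1005, 1116 and 1067 without GLK1-SRDX replicate 1, 2 or 3. Of the calls 61.3% were higher, against 90% of 1550 calls from the series values. Of the 45 named genes called besides GLK1 and GLK2, 35 passed whichever array was left out, and ACT2, AOC1, BHLH101, CAO, CAT1, KAT1, M17, PR1, PRR5 and RVE1 did not. The most calls, 9, ended without glk1 glk2 replicate 2. Passing lists numbered 9, and 5 without glk1 glk2 replicate 2. The Calvin cycle list did not pass without glk1 glk2 replicate 1, 2 or 4 (medians -0.13, -0.084 and -0.20, adjusted p = 0.0605, 0.0804 and 0.0829). Nor did the clock list without these or GLK1-SRDX replicate 3 (medians -0.22, -0.21, -0.27 and -0.22, adjusted p = 0.0566, 0.113, 0.0814 and 0.0553). The flavonoid list did not pass without glk1 glk2 replicate 2 (median 0.28, adjusted p = 0.0682) or the iron list without replicate 2 or 4 of glk1 glk2 (medians 1.70 and 1.65, adjusted p = 0.0545 and 0.0829). Without glk1 glk2 replicate 3 the Calvin cycle median was -0.33 and the clock median -0.46. Over all alternatives the adjusted p of these lists ran from 1.60e-06 to 0.832, 0.00349 to 0.461, 0.00124 to 0.883 and 0.00639 to 0.781.

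Both comparisons against wild type share the 4 wild-type arrays. Their log2 fold changes correlated across 20640 genes at r = 0.54 (genes are not independent replicates), and their covariance was 0.132. In 100 simulated regroupings with no effect, which ignored the pairing of wild-type and glk1 glk2 numbers, the median r was 0.52. The covariance had a median of 0.0317 and a range of -0.0332 to 0.157, which holds the observed value. This planned simulation therefore did not show a likeness beyond shared controls. With the pairs kept, a simulation chosen after the data were seen gave each pair and each GLK1-SRDX array a random sign in 100 draws. The median r was then 0.16, with a range of -0.34 to 0.58. The covariance had a median of 0.00707 and a range of -0.0251 to 0.0353, below the observed value. The pairs were taken from these same data, so this simulation cannot decide the question by itself. Of the genes called, 192 were higher in both lines (35.7 for independent lists) and 71 were lower in both (14.5 for independent lists), while 15 were called in opposite directions. Root markers were lower in both lines too (medians -0.76 and -0.98), and these counts take no account of that. The simulations gave at most 0 shared calls in limma without the pairs and 2 with them. PORA and MES18, a methyl esterase, were among the genes that fell in both lines. With the wild-type arrays split between the comparisons in each of 6 ways, r ran from 0.28 to 0.45, the mean covariance was 0.103 and 2 to 8 genes were called the same way in both. The 263 genes called the same way numbered 67, 86 and 121 without wild-type replicate 1, 2 or 4, 112, 129 and 1393 without glk1 glk2 replicate 1, 2 or 3, and 154, 107, 139 and 163 without GLK1-SRDX replicate 1, 2, 3 or 4. Of all arrays, glk1 glk2 replicate 3 held the highest root-marker level (1.09).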

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

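The tests of the SUP signal's spread and of the falls shared with GLK1-SRDX were chosen only after the result was seen. Of 411 sets of 4 arrays examined (116 genes and 21 lists), 18 held an array far from the other 3, where chance gives about 20.6. The values that follow are the gap to the nearest array over the range of the 4. The Calvin cycle list was lowest on glk1 glk2 replicate 3 (0.933) and the starch and sugar list highest on wild-type replicate 4 (0.906). In wild type, NEET (0.944), APX1 (0.854) and AOC1 (0.908) were lowest on replicate 3, ALMT6 lowest (0.864) and PIF1 highest (0.935) on replicate 4, and COR6.6 lowest on replicate 1 (0.883). In glk1 glk2, SWEET11 (0.830), PORB (0.964) and SOC1 (0.851) were lowest on replicate 3, and CORI3 (0.938) and NAP (0.945) highest on replicate 4. In GLK1-SRDX, DFR (0.846), TT19 (0.911) and UF3GT (0.918) were highest on replicate 2, and on replicate 4 SUP was lowest (0.980) and NCED3 highest (0.916). Probes without an AGI locus were tested apart, 4170 of them, and 24 changed in glk1 glk2 against wild type, 189 in GLK1-SRDX against wild type and 180 between the lines.

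The SUP probe stood at a mean of 7.03 on the GLK1-SRDX arrays, where the SD was 0.284. Activation across the chromosome region around SUP is argued against, since 1 of the 10 nearest tested genes was called higher (RLP37, at 0.92). RLP37 is the nearest tested gene on its side of SUP, and activation limited to SUP and its direct neighbour is not decided by this count. On the other side of SUP, some of the 10 were called lower, at -0.65, -0.48 and -0.94 (limma adjusted p = 0.0465, 0.00652 and 0.0479). Hybridization of the transgene's repression domain, which derives from SUP, and expression of SUP itself cannot be told apart, because probe sequences are not used here. The spread between the arrays allows either.

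Root markers were lower in both lines. If the harvested seedlings held less root, other genes that follow the root-marker level within groups would be lower as well. The 200 such genes outside the list had a median log2 fold change of -1.16 in GLK1-SRDX (jackknife SE 0.397, with -1.25 predicted from the markers), so a lower root share is a candidate explanation there. In glk1 glk2 the median was -0.97 (SE 0.750, with -0.96 predicted), and the spread of its arrays keeps this open. A smaller root as a trait of the lines would give the same values and was not tested.

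The 23 genes with a fitted fall of at least 8-fold in glk1 glk2 included LHCB1.4 at -7.87, which stood at -0.12 in GLK1-SRDX. GLK2, itself mutated, is among the 23. The fitted fold takes no account of background. Among others, BHLH100, LDOX and MES18 were above background on 0 glk1 glk2 arrays, and BHLH38, NAS2 and ZIP8 on 1 of 4. By its bound ZIP8 was at least 7.64-fold lower. For a linked chromosome segment that differs from wild type, 0 of the 23 had another within 25 tested loci. The median of 10000 random sets was also 0 and their 95th percentile 4. No clustering within that window was seen, but a count equal to the random median cannot decide the question. A longer segment was not tested. A loss of expression that the chimeric repressor also brings about stays open, with 30.4% of the 23 called lower in GLK1-SRDX. Sequence differences under single probes were not tested.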

How the results depend on the processing

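Chosen after the data were seen were the replicate block on 8 arrays, leaving out both arrays numbered 4 of wild type and glk1 glk2, the root-marker covariate, each slide alone, the random slide block and the median signals for normexp. Median scaling moved the median of all genes by 0.19 in glk1 glk2 and 0.18 in GLK1-SRDX, and the series values by -0.19 and 0.10 (0.29 between the lines), and changes are relative to these shifts. In glk1 glk2 the 671 changed genes became 1654 with median scaling, 443 without a filter, 136 with the series values, 111 with only the 2 groups, 132 at 2-fold, 225 without both arrays numbered 4, 20 on slide 1 and 0 on slide 2 in limma (298 at an unadjusted p under 0.05). In GLK1-SRDX the 2972 became 909 with the series values and 876 at 2-fold. Between the lines the 1911 became 1154 with median scaling, 1271 with only the 2 groups, 488 at 2-fold and 3561 with the root-marker covariate. Genes called the same way in both lines became 1025 with median scaling, 151 without a filter, 27 with the series values and 98 without both arrays numbered 4. The 2-fold threshold lowers a count by construction, and the cause was not tested for the others.

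With the replicate block on 12 arrays the counts were 1300, 4521 and 3085 genes and 605 shared calls, and on the 8 paired arrays 1365. Deviations of GLK1-SRDX arrays 1 to 4 correlated with same-numbered wild-type arrays at -0.064, -0.20, 0.26 and 0.0088. With glk1 glk2 they correlated at -0.0080, 0.20, 0.58 and -0.096. Number 3 aside, most were not above 0.1, so the GLK1-SRDX numbers were not taken as pairs. A call lost under that block (the iron list between the lines, median 2.09, adjusted p = 0.0645) is not a weaker effect. Besides the calls given with the glk1 glk2 comparison, the 8-array block changed no call of a named gene or of the 7 lists that had passed. Lists that had not passed were not followed singly under it.

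GLK1 in GLK1-SRDX passed with median scaling (1.03), normexp (0.87), the replicate block, the random slide block and the 2 groups alone (0.85 in each) and without both arrays numbered 4 (0.97). GLK2 passed with those (0.81, 0.67, 0.62 in each of the 3 and 0.72), and at 0.62 with probes above background on all arrays and with the variance trend. AKT1 in GLK1-SRDX passed in 10 of 25 alternatives (adjusted p from 0.0124 to 0.286), with quantile normalization, median scaling, normexp, the variance trend, the 2 groups alone, the replicate block, the random slide block, without both arrays numbered 4 and without glk1 glk2 replicate 3 or 4. GLK1 in glk1 glk2 lost its call on slide 1 (-2.21) and slide 2 (-2.24), and GLK2 on slide 2 (-7.26). With an estimated correlation camera passed 0, 0 and 0 lists (3, 1 and 1 at an unadjusted p under 0.05), against 6, 2 and 6 by fry's direction test and 10, 13 and 15 by its mixed test. Of the lists that camera passed, fry's direction test did not pass chlorophyll (adjusted p = 0.277) and root genes (0.247) in glk1 glk2. In GLK1-SRDX it did not pass antenna (0.411), core (0.416), guard-cell (0.0617), iron (0.0617) and root genes (0.201). Between the lines it did not pass chlorophyll (0.0609), Calvin cycle (0.433), clock (0.0609) and iron genes (0.0609). Between the lines, normexp ended the flavonoid and iron list calls, as did requiring signal on all arrays (medians 0.11 and 0.021), which removes BHLH100, DFR and LDOX because they were at background on glk1 glk2 arrays and so selects against the difference tested. Median scaling ended that of the clock list (-0.22) and the series values that of the iron list (2.38). Leaving out both arrays numbered 4 ended those of the Calvin cycle (-0.20), clock (-0.27) and iron lists (1.65) and, in GLK1-SRDX, of the antenna (-0.16) and core lists (-0.13). The root-marker covariate ended the root list's call in both lines by construction (-0.20 and -0.24). Other list medians moved by over 1.5 times with a scaling or normexp, camera's direction staying as it was, and with median scaling and the series values they moved nearly as all genes did. In glk1 glk2 median scaling gave -0.094 for chlorophyll and 0.44 for oxidative stress genes, the series values -0.47 and 0.045, and flavonoid genes stood at -0.12 with quantile normalization, -0.12 with normexp and -0.39 with the series values. In GLK1-SRDX median scaling gave 0.43 for oxidative stress genes, and the series values -0.11 for antenna, -0.100 for core and -0.11 for guard-cell genes. Between the lines the series values gave 0.83 for chlorophyll, 0.76 for core and 0.69 for flavonoid genes. Normexp brought iron genes to -1.68, -1.08 and 0.64 in the 3 comparisons, flowering markers to -0.72 in GLK1-SRDX and -0.74 between the lines, core genes to -0.10 in GLK1-SRDX and flavonoid genes to 0.16 between the lines. The correlation of the lines moved to 0.38 with split controls. Of the 151 values of named genes, 141 of 151 kept direction and call with quantile normalization, 131 of 151 with median scaling, 128 of 151 with normexp, 129 of 151 without a filter, 103 of 151 with the series values, 119 of 151 with only the 2 groups and 147 of 151 with the variance trend.

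Among named genes, signs turned for uncalled genes only. OST1 (0.12, median scaling) and SLAC1 (-0.027, series values) in glk1 glk2 and SLAC1 in GLK1-SRDX (0.032, median scaling) turned by the move of all genes, not relative to it. The cause was not tested for the others. In glk1 glk2 these were AKT1 (0.20) and AKT2 (-0.27) with the root-marker covariate. In GLK1-SRDX they were SLAC1 (0.047 quantile, 0.10 normexp), OST1 (-0.055 normexp, -0.00053 without both arrays numbered 4), AKT2 (0.078 without both) and GORK (0.058 with the covariate). Leaving out single arrays, AKT2 ran from -0.047 to 0.78 and OST1 from -0.19 to 0.0063 in glk1 glk2, and from -0.47 to 0.078 and -0.020 to 0.11 in GLK1-SRDX. GLK1 in GLK1-SRDX ran from 0.76 to 0.97 and GLK2 from 0.49 to 0.72. Genes changed ran from 229 to 3177, 1523 to 4444 and 1005 to 2684 in the 3 comparisons, passing lists from 7 to 12 in glk1 glk2 and 5 to 10 between the lines, and shared calls from 67 to 1393. Low signal over background limits BHLH100, LDOX, AP1, SUP and other genes not well above background in a group.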

Other observations

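The genes named in this paragraph were chosen after their values were seen. FRO2, the ferric chelate reductase of the root and a member of the iron-deficiency list, fell in glk1 glk2 and is among the 5 members already counted there. It was lower (at least 15.1-fold, adjusted p = 0.00947). NAS2, a nicotianamine synthase and not in the list, fell as well (at least 8.94-fold, adjusted p = 0.0112), as did ZIP8, a metal transporter of the ZIP family (at least 7.64-fold, adjusted p = 0.00512). They were above background on 3, 1 and 1 of 4 glk1 glk2 arrays. In GLK1-SRDX, ZIP8 (at least 5.94-fold, adjusted p = 0.0154) and NAS2 (at least 4.62-fold, adjusted p = 0.0436) fell, each above background on 3 of 4 arrays, and FRO2 did not pass (log2 fold change -1.76, adjusted p = 0.0893). The root markers were lower in both lines beside these genes. BBX16, a B-box protein, fell in both lines (log2 fold change -3.59, adjusted p = 0.000677 in glk1 glk2 and -1.71, adjusted p = 0.0115 in GLK1-SRDX), as did FUM2, the cytosolic fumarase (-2.42, adjusted p = 0.000472 and -3.15, adjusted p = 0.000120), IAA29, an auxin-response repressor (-1.99, adjusted p = 0.0302 and -3.08, adjusted p = 0.00106), and TIM17-1, of mitochondrial protein import (-3.53, adjusted p = 2.48e-05 and -2.84, adjusted p = 0.000151). For all 7 the arrays of either line did not overlap those of wild type.

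The tests of other splits were planned. Each other split of the 8 arrays of a comparison, with the third group kept, was counted. For GLK1-SRDX against wild type, 1 of the 35 splits, the real one, gave as many as 2972 genes, and the highest other gave 0. For GLK1-SRDX against glk1 glk2 the real split alone (1 of 35) reached 1911 genes, with 2 in the highest other. In the other splits a real difference falls within the groups and lowers the count. A share of 1 in 35 is the smallest that these splits allow. It is under 0.05, so chance is argued against in both comparisons but not excluded. The slide of GLK1-SRDX follows the real split in both, and its share is not separated by this count. For glk1 glk2 against wild type, 3 of 35 splits gave as many as 671 genes, so chance is not excluded. The highest other split gave 4429 genes, which points to a structure of the samples. It parted the arrays by root-marker level, with -1.54 to 0.305 on wild-type replicate 4 and glk1 glk2 replicates 1, 2 and 4. The other arrays of the comparison stood at 0.681 to 1.09. The next split, with 1890 genes, did not part the levels so. Both larger splits placed the arrays numbered 4 of wild type and glk1 glk2 together and glk1 glk2 replicate 3 on the other side. Whether the root share gave these counts was not tested. Of the 8 splits that part every pair of equal numbers, the real one gave 671 and the others at most 0, and with the replicate block 1365 and at most 0, which are too few splits for a share under 0.05. Numbers of passing lists as large as the real 7, 7 and 9 came from 21, 18 and 10 of the 35 splits, with 14, 16 and 12 in the highest other, so chance is not excluded for the number of lists.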
